A study of Mus musculus with 36 samples.

How the data were processed

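The samples were RNA precipitated from mouse hemibrain homogenates with anti-HA antibody or IgG, sequenced as 3' libraries by MARS-seq, per the labels' protocols. Reads were assigned to genes on the mm9 build, per the submitters' processing notes. The aligner and the counting program are not stated. The deposited tables give raw counts per gene and library, per the file headers, beside log2 fold changes, adjusted p-values and a pass mark that the authors computed with DESeq, per the sheet name. The steady-state table lists 12580 genes in 24 libraries of Sall1 and Lyve1 mice, and the Lyve1 table lists 12403 genes in 20 libraries at steady state and after LPS. The values are whole numbers, and the lowest maximum count of a listed gene is 6 in both tables, so the authors' listing leaves out genes with few counts. The tables share 12 libraries, in which 0 counts differ. Deposited normalized values of the same libraries, gene lists for figures and 28 library columns of no sample here were not used. Libraries were assigned to groups by the names in the file headers, per the labels, and are named by group and the 2 numbers of their column. The 2 HA and 2 IgG libraries of LPS-treated Sall1 mice were not analysed here.

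Gene symbols were used as the files give them. In the reference table, 12021 symbols of the steady-state table were current names, 536 were synonyms and 23 did not match, and the Lyve1 data had 11865, 516 and 22 of these. Genes that overlap or share sequence with a near copy, such as Atrip with Trex1 and the Saa and H2 genes, are uncertain, because the treatment of shared reads is not stated.

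Each table was analysed on its own with R 4.3.3. Genes with low counts were removed with filterByExpr by group (minimum count 10, minimum total 15), which left 9619 genes in the steady-state table and 9680 in the Lyve1 table, with 99.04% of the counts in each. Counts were scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood, robust), with the 4 groups of a table in 1 fit, 20 and 16 residual degrees of freedom and a common biological coefficient of variation of 0.21 and 0.182. Contrasts were tested with the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 passed. Interactions compared the HA to IgG ratio between lines or between treatments. The standard error of a log2 ratio is its size over the square root of F. All adjusted p of genes in the text are from edgeR unless another tool is named. For a gene with 0 counts over a group, the ratio was computed against a floor of 3 counts over the group. For a gene with 1 to 3 counts, the ratio has an exact 95% interval. Floors and intervals cover counting error only.

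The 24 gene lists were written down before the data were examined, as was the rule for naming genes. They hold markers of microglia, border macrophages, neurons, astrocytes, oligodendrocytes and their precursors, endothelium, mural cells, fibroblasts, choroid plexus and ependyma, monocytes, neutrophils, lymphocytes and erythroid cells. They also hold MHC class II, NF-kB and cytokine, interferon-stimulated, disease-associated microglial, complement, lysosomal, immediate early and heat shock, glucocorticoid and metallothionein, mitochondrially encoded and ribosomal protein genes. Some lists describe cells and programmes that overlap, and brain tissue expresses most of their members. The 20 lists with at least 3 tested members were tested per contrast with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of the contrast. Camera with an estimated correlation and fry were alternatives.

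The rule named, per contrast, up to 12 genes per direction with the largest change among those that passed, changed at least 2-fold, averaged at least 10 counts per library in the higher group and had groups that did not overlap. For interactions the condition on overlap was dropped. Up to 4 members of each list with the smallest p, and the genes behind the transgenes, were added. Unnamed gene models and joined symbols were left out. Genes outside this rule are named only where they complete a count of 5 or fewer, and these were chosen after their values were seen.

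The alternatives set at the same time were DESeq2 size factors, library totals without TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, only the groups compared, a replicate block, libraries under a set share of the median total left out, and each library left out in turn. Chosen after seeing the data were counts summed over libraries of a group that share a first number, a term for Y-linked counts, Sall1 libraries with Y-linked counts left out (for the enrichment between lines also with DESeq2 and limma-voom), Sall1 libraries with the first number 3 left out, Sall1 IgG libraries 2-1 and 2-2 left out, and all alternatives for the IgG comparison of the lines. A library counted as holding Y-linked counts with at least 10 counts of Ddx3y and Eif2s3y together.

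The procedure was tested on simulated counts with known changes. Of genes changed 2-fold, 76.1% were recovered in the simulated Sall1 HA to IgG contrast, 64.2% for Lyve1, 35.8% for the interaction of the lines, 64.2% for LPS in HA and 47.8% for the LPS interaction. Of the calls made in these contrasts 4.38%, 7.09%, 3.37%, 6.92% and 8.08% were false, and 5.15% for HA between lines, so the share exceeded 5% in 4 contrasts. Of 9 raised lists 9 were called, and of 180 unchanged lists 0 were called by camera. The simulated counts were drawn independently for each gene and library, without correlation between genes or likeness of libraries that share a first number. The shares of false calls and of called lists therefore do not measure the error under such correlation. At totals of 362063 to 1696679 counts per library, 9 members of the border macrophage list passed the filter at steady state. Libraries of a group differed by more than counting error, with chi-square per degree of freedom between 1.76 and 18.1. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.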

Results

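Ribosome-bound RNA was measured in mouse hemibrains in which the ribosomal protein Rpl22 carries an HA tag after Cre recombination (Ribo-tag). Cre was assembled from 2 fragments, so that the tag was limited to cells expressing both driver genes. Cx3cr1 with Sall1 marks microglia, and Cx3cr1 with Lyve1 marks macrophages at the borders of the brain. Per the labels, precipitates with anti-HA antibody and control precipitates with IgG, which hold background RNA of the tissue, were made from each brain. Which HA and IgG libraries belong to the same brain is not stated, so they were compared as unpaired. The 36 samples fall into 8 groups. At steady state there were 6 HA and 6 IgG libraries of each line, and 12 h after an injection of lipopolysaccharide (LPS, 2.5 mg/kg) there were 4 HA and 4 IgG libraries of Lyve1 mice. The 2 HA and 2 IgG libraries of LPS-treated Sall1 mice were not analysed here. Library totals ranged from 362063 counts, in an IgG library after LPS, to 1696679 counts. At steady state they were 1252785 to 1655096 in Sall1 HA, 857553 to 1696679 in Sall1 IgG, 603827 to 1495746 in Lyve1 HA and 890640 to 1474838 in Lyve1 IgG. After LPS they were 682445 to 1380452 in HA and 362063 to 976737 in IgG. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values may measure technical spread. Errors of log2 ratios are standard errors of the fit, and those of counts scaled to library size (CPM) are standard deviations.

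In Sall1 mice, the comparison of HA with IgG asked which transcripts were bound to tagged ribosomes above background. The microglial membrane protein gene Tmem119 stood at 242 ± 38.5 CPM in HA and 32.7 ± 8.48 CPM in IgG (n = 6 each). Its log2 ratio was 2.89 ± 0.19 (adjusted p = 1.47e-12). Trem2, a lipid receptor of microglia, stood at 153 ± 38.7 against 26.4 ± 1.81 CPM, and C1qb, a chain of complement C1q, at 820.5 ± 293 against 111 ± 15.95 CPM. The matrix protease gene Mmp9 had the largest ratio of the named genes (log2 3.29 ± 0.79, adjusted p = 0.00957). It was followed by Tmem119, C1qb (2.88 ± 0.25), Bin2 (2.84 ± 0.32), the lysosomal protease gene Ctss (2.75 ± 0.32), Crybb1 (2.74 ± 0.22), Rnase4 (2.72 ± 0.28) and Susd3 (2.66 ± 0.37). Laptm5 (2.645 ± 0.19), Aif1 (2.58 ± 0.29), C1qc (2.57 ± 0.17) and Trem2 (2.53 ± 0.18) came next. The driver gene Cx3cr1 was enriched by 2.34 ± 0.56 on the log2 scale (adjusted p = 0.00832), or by 1.30 without Sall1 HA library 1-2, while Sall1 itself did not pass (0.55 ± 0.31, adjusted p = 0.28). Of 9619 genes tested, 943 passed, 463 higher and 480 lower in HA, and 110 of these were at least 2-fold higher and 53 at least 2-fold lower. Without Sall1 IgG library 1-1 the count was 567, and with only the groups compared it was 541.

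**Figure D1:**
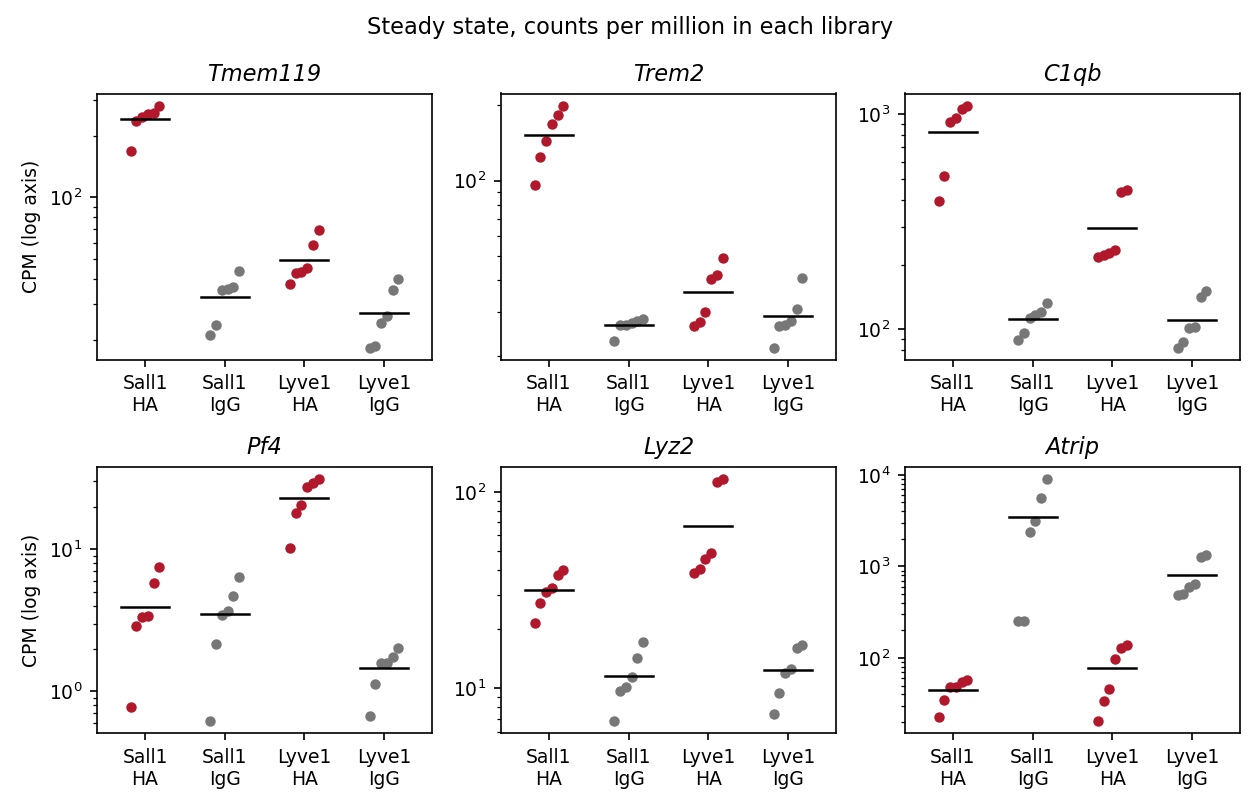
CPM on a log axis of 6 genes in each steady-state library, with the line at the mean of the 6 libraries of a group. Tmem119 averaged 242 CPM in Sall1 HA and 49.4 CPM in Lyve1 HA, and Pf4 averaged 22.8 CPM in Lyve1 HA and 3.95 CPM in Sall1 HA.

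The genes most reduced in Sall1 HA were Atrip, a partner of the DNA damage kinase Atr (-6.27 ± 0.82), the overlapping exonuclease gene Trex1 (-4.62 ± 0.69, or -4.02 without Sall1 IgG library 2-2), Usp24 (-2.11 ± 0.31) and the laminin gene Lamb1 (-1.48 ± 0.24). Atrip and Trex1 overlap in the genome, so the share of reads of each is uncertain. Without Sall1 IgG libraries 2-1 and 2-2, which held the highest Atrip, an alternative chosen after seeing the data, the 3 calls held, with -5.08 for Atrip, -3.17 for Trex1 and -1.38 for Usp24, and limma-voom gave -5.44 for Atrip, -3.62 for Trex1 and 1.75 for Cx3cr1. With the Sall1 libraries that hold Y-linked counts left out, an alternative chosen after seeing the data that keeps 2 HA and 2 IgG libraries, 69 genes passed, and C1qb (2.29), Rnase4 (2.07), Laptm5 (1.95) and C1qa (1.87) kept their calls at smaller ratios. The calls of Mmp9 (2.14), Ctss (1.83), Aif1 (1.78), Cx3cr1 (0.35), Atrip (-2.32), Trex1 (-1.03), Usp24 (-0.799) and Lamb1 (-0.796) were lost, with adjusted p between 0.0583 and 0.861. Lost too were those of Itgb2 (1.60), Apoe (0.72), B2m (1.51), Ctsd (0.50), Ptgds (0.58), Igfbp2 (0.84), H2-DMa (0.47), Bst2 (0.87), Psmb8 (0.61), Ifi27l2a (0.87) and Ttr (0.68), whose ratios over all libraries are given in the lists that follow. Summing libraries that share a first number gave 163 genes and ended the calls of Mmp9 (3.30), Cx3cr1 (2.35), Trex1 (-4.62), Itgb2 (1.83), B2m (1.52), Ctsd (0.70), H2-DMa (0.87), Bst2 (1.13), Psmb8 (0.88) and Ifi27l2a (0.98), with adjusted p between 0.0621 and 0.206. These ratios stayed close to those of the main fit.

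The microglial list had the smallest p in Sall1 HA. Of its 25 tested members, 21 were higher, 0 lower and 4 did not pass, with 22 higher adjusted over the list alone. Their median log2 ratio was 1.77 (camera adjusted p = 2.04e-55, adjusted p = 3.93e-06 with an estimated correlation). Selplg (2.15 ± 0.15) was among its strongest members. Of 5 complement genes tested, C1qa (2.46 ± 0.18), C1qb, C1qc and the integrin gene Itgb2 (1.82 ± 0.47) were higher, the same 4 as adjusted over the list alone (median 2.46, adjusted p = 1.64e-05 with an estimated correlation). The lysosomal list had 9 of 17 members higher, among them Grn (1.496 ± 0.15), Ctsz (1.35 ± 0.16), Laptm5 and Ctss, and it kept its upward shift with an estimated correlation (adjusted p = 3.82e-05). The list of genes induced in disease-associated microglia had 7 of 13 members higher, 8 adjusted over the list alone, with the tetraspanin gene Cd9 (1.49 ± 0.19), B2m (1.54 ± 0.28), Apoe (0.81 ± 0.12) and Ctsd (0.69 ± 0.13) leading (adjusted p = 5.49e-05 with an estimated correlation).

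Several other lists moved less in Sall1 HA. The border macrophage list, with 9 of its 36 members tested, did not shift (adjusted p = 0.687), and neither did the lists for neurons (0.748), astrocytes (0.687), oligodendrocytes (0.588), oligodendrocyte precursors (0.903), endothelium (0.358), mural cells (0.539), choroid plexus and ependyma (0.0568), NF-kB and cytokine genes (0.748), immediate early genes (0.515) or glucocorticoid targets (0.223), all camera adjusted p. Ttr of the choroid plexus was the only member of its list to pass (0.87 ± 0.12). Ptgds (0.61 ± 0.10) and Igfbp2 (0.73 ± 0.13), the 2 fibroblast genes that passed of 9, and H2-DMa (0.86 ± 0.20), the 1 of 6 MHC class II genes, were higher. The fibroblast list shifted with camera adjusted p = 0.00364, lost with an estimated correlation (adjusted p = 0.0959), and the MHC class II list with 0.0433, lost likewise (adjusted p = 0.436). Among 10 interferon-stimulated genes, Bst2 (1.11 ± 0.28), Psmb8 (0.87 ± 0.24) and Ifi27l2a (0.99 ± 0.27) were higher, and the list's call (0.02) was lost with an estimated correlation (adjusted p = 0.423). The call of Ifi27l2a was lost without Sall1 IgG library 1-1 (0.91, adjusted p = 0.0637) or 1-2 (0.92, adjusted p = 0.0545), or without the Sall1 libraries with the first number 3 (adjusted p = 0.0567). Ribosomal protein genes, 7 of 71 higher, and the neutrophil list, with 3 members tested, also lost their calls with an estimated correlation (adjusted p = 0.622 and adjusted p = 0.0893). Monocyte and erythroid genes were too few to test (1 and 2 members), 0 lymphocyte genes passed the filter and 0 mitochondrially encoded genes were listed.

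In Lyve1 mice, the same comparison addressed the border macrophages. The chemokine gene Pf4, typical of these cells, stood at 22.8 ± 8.03 CPM in HA and 1.46 ± 0.487 CPM in IgG (n = 6 each), a log2 ratio of 3.84 ± 0.43 (adjusted p = 4.71e-07). The lysozyme gene Lyz2 stood at 67.1 ± 36.9 against 12.3 ± 3.60 CPM (2.46 ± 0.29). The gelatinase genes Mmp9 (4.77 ± 0.77) and Mmp2 (3.33 ± 0.57) were also strongly enriched, by 3.81 and 2.73 without Lyve1 HA library 2-2 and by 3.66 and 2.52 with limma-voom. They were followed by Sh3bgrl (2.10 ± 0.47), the RNA-binding protein gene Hnrnpa3 (2.07 ± 0.65), the calcium-binding protein gene Calb1 (1.88 ± 0.46), Ifitm3 (1.69 ± 0.34), Spock3 (1.62 ± 0.32), B2m (1.56 ± 0.29), the translation factor gene Eif3e (1.55 ± 0.32) and the potassium channel partner gene Kcnip4 (1.53 ± 0.37). Calb1, Spock3 and Kcnip4 are known from neurons. Of 9619 genes, 2472 passed, 1121 higher and 1351 lower, with 164 at least 2-fold higher and 247 at least 2-fold lower. Lower in HA were Atrip (-3.38 ± 0.73), Trex1 (-2.25 ± 0.66), the centrosomal gene Cep290 (-2.24 ± 0.76), the laminin gene Lamc1 (-1.995 ± 0.26), the cadherin gene Fat1 (-1.78 ± 0.29) and the dynein gene Dync1h1 (-1.77 ± 0.18). The call of Cep290 was lost without Lyve1 HA library 1-1 (-2.15), 1-2 (-2.22), 2-1 (-1.99) or 3-1 (-2.23), or IgG library 3-2 (-1.83), with adjusted p between 0.0548 and 0.0921. Summing libraries that share a first number gave 1005 genes and ended the calls of Hnrnpa3, Atrip, Trex1 and Cep290 named here, and of Igfbp4, Rtn4rl1, Ctsd, Bst2 and Cd74 in the lists that follow, with adjusted p between 0.0775 and 0.179. The driver gene Lyve1 had too few counts to be tested, with 3 to 12 counts per HA library and 0 to 2 per IgG library.

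The border macrophage list had 9 tested members. Pf4, Lyz2, the carbonyl reductase gene Cbr2 (1.41 ± 0.38) and Igfbp4 (0.42 ± 0.14) were higher, the complement gene C4b was lower (-1.04 ± 0.25) and 4 did not pass (4 higher and 2 lower adjusted over the list alone). Its median was 0.30 and its mean 0.757, and the camera call (adjusted p = 0.0373) was lost with an estimated correlation (adjusted p = 0.304). The call of Igfbp4 was lost without Lyve1 HA library 2-1 (0.40) or 3-2 (0.41), or IgG library 1-1 (0.41), 2-1 (0.41), 3-1 (0.41) or 3-2 (0.39), with adjusted p between 0.051 and 0.0633, and without a filter on low counts (adjusted p = 0.0503).

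Microglial genes were enriched less than in Sall1 mice. Of 25, 8 were higher, among them Fcer1g (1.52 ± 0.24), Ltc4s (0.94 ± 0.20), Sparc (0.62 ± 0.14) and Tmem119 (0.87 ± 0.20), and Rtn4rl1 was lower (-0.58 ± 0.16). The list's shift (median 0.28, camera adjusted p = 0.0373) was lost with an estimated correlation (adjusted p = 0.457). The complement genes C1qc (1.23 ± 0.17), C1qb (1.42 ± 0.24) and C1qa (0.80 ± 0.18) were higher of 5, with adjusted p = 0.216 for the list with an estimated correlation. In the disease-associated list 6 of 13 were higher, led by Apoe (1.27 ± 0.12), B2m (1.56 ± 0.29), Cd63 (0.75 ± 0.14) and Cd9 (0.79 ± 0.20), and Ctsd was lower (-0.41 ± 0.13). This shift held with an estimated correlation (adjusted p = 0.0415). In the lysosomal list 6 of 17 were higher, led by Grn (0.81 ± 0.16), Ctsz (0.80 ± 0.17) and Cd68 (1.42 ± 0.34), and the call was lost (adjusted p = 0.328 with an estimated correlation).

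Ribosomal protein genes were higher in Lyve1 HA in 25 of 71 cases and 31 adjusted over the list alone, with a median of 0.54. The list's call (camera adjusted p = 1.68e-09) was lost with an estimated correlation (adjusted p = 0.375). Of 9 fibroblast genes 6 were higher, led by Ptgds (0.71 ± 0.10), Igfbp2 (0.76 ± 0.13) and Apod (0.69 ± 0.14), with adjusted p = 0.162 for the list with an estimated correlation. Interferon-stimulated genes included Ifitm3 and Bst2 (1.19 ± 0.29), and the list's shift was lost too (adjusted p = 0.417 with an estimated correlation). The MHC class II invariant chain gene Cd74 was the 1 of 6 tested in its list that passed (1.42 ± 0.41, adjusted p = 0.0131), and its call was lost without Lyve1 HA library 2-1 (0.64, adjusted p = 0.16) and with only the groups compared (1.46, adjusted p = 0.0847). The 22 genes of the neuronal list, which does not hold Calb1, Spock3 or Kcnip4, did not shift (camera adjusted p = 0.38).

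**Figure D2:**
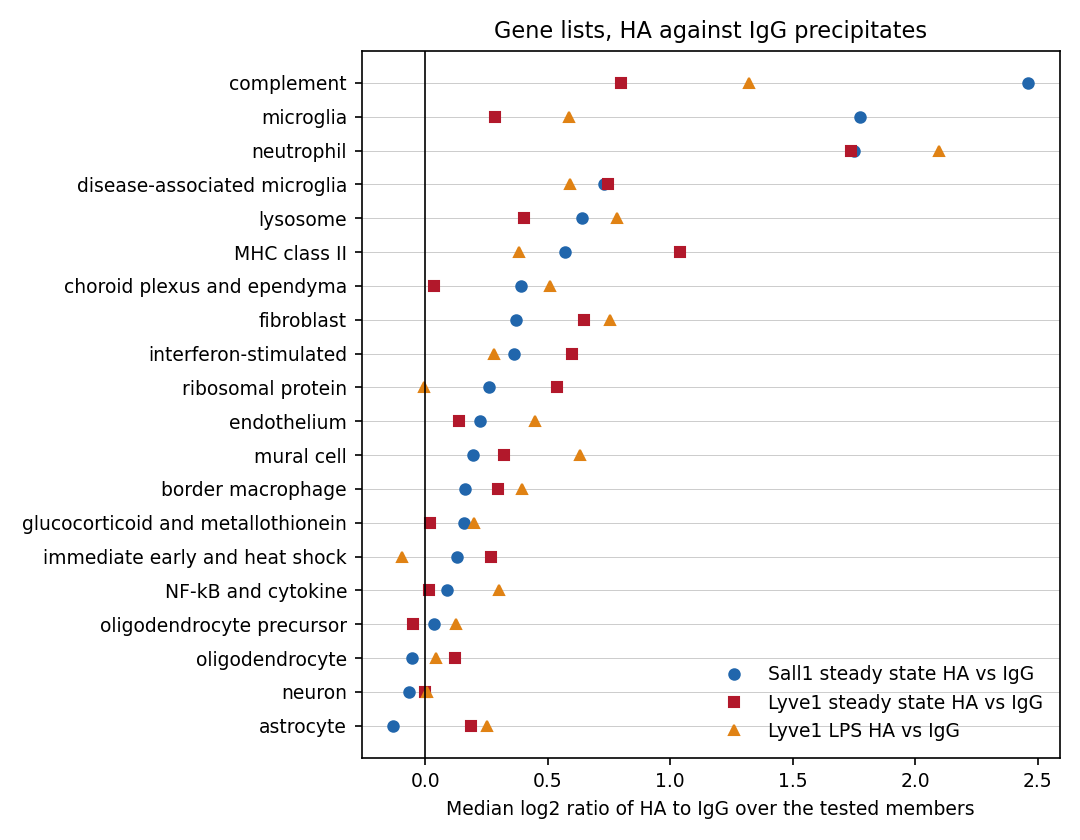
Median log2 ratio of HA to IgG over the tested members of each gene list with at least 3 of them, for 3 comparisons. The microglial list stood at 1.77 in Sall1 mice and 0.28 in Lyve1 mice at steady state.

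Set against each other at steady state, the HA precipitates of Sall1 mice held more of many microglial transcripts than those of Lyve1 mice. Of the border macrophage genes tested, Pf4 was lower in Sall1 HA, and so was Lyz2, whose call several settings ended. Tmem119 was higher in Sall1 HA by 2.30 ± 0.18 on the log2 scale (adjusted p = 6.74e-10, n = 6 each). The crystallin genes Cryba4 (2.38 ± 0.40) and Crybb1 (2.04 ± 0.21), Laptm5 (2.18 ± 0.19), Bin2 (2.14 ± 0.31), the oxidase subunit gene Ncf1 (2.12 ± 0.21), Trem2 (2.05 ± 0.18), Lag3 (2.01 ± 0.30) and the fructose transporter gene Slc2a5 (1.94 ± 0.31) were higher as well. Pf4 (-2.46 ± 0.36) and the ribosomal protein gene Rpl7 (-1.09 ± 0.21) were lower. Sall1 did not pass (0.79 ± 0.33, adjusted p = 0.236). In all, 135 genes passed, 119 higher and 16 lower in Sall1 HA, with 69 at least 2-fold higher and 5 at least 2-fold lower. The Sall1 libraries numbered 1-1 to 2-2 held Y-linked counts and the Lyve1 libraries at steady state did not. A term for this pattern, chosen after seeing the data, gave 1775 genes, 795 higher and 980 lower, of which 116 were among the 135. Leaving these Sall1 libraries out keeps only Sall1 HA libraries 3-1 and 3-2, and gave 900, 420 higher and 480 lower. The excess of higher genes therefore depends on this setting. On the second principal component, with 18.9% of the variance, libraries 3-1 and 3-2 stood at -52.7 and -25.9. The other HA libraries stood at -18.1 to 20.7. With the term, too, the contrast rests on how Sall1 libraries 3-1 and 3-2 differ from the others. A trait of these libraries is thus not told apart from the Y-linked pattern. Summing libraries that share a first number gave 29.

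Of 25 microglial genes, 17 were higher in Sall1 HA and 22 adjusted over the list alone, with 0 lower (median 1.49, camera adjusted p = 1.78e-53, adjusted p = 3.25e-06 with an estimated correlation). Selplg, an adhesion ligand, was among them (1.59 ± 0.15). Of 9 border macrophage genes, Pf4 and Lyz2 (-1.08 ± 0.26) were lower and 3 adjusted over the list alone, with a median of -0.70 (adjusted p = 0.00834 with an estimated correlation). The call of Lyz2 was lost without Lyve1 HA library 2-1 (-0.86) or 2-2 (-0.90) or Sall1 HA library 1-1 (-1.05), 2-1 (-1.08) or 3-2 (-1.003), with adjusted p between 0.0565 and 0.107, with only the groups compared (adjusted p = 0.0827) and without the Sall1 libraries with the first number 3 (adjusted p = 0.0643). The complement genes C1qc (1.49 ± 0.16), C1qa (1.59 ± 0.18) and C1qb (1.47 ± 0.23) and the lysosomal genes Laptm5, Lgmn (0.82 ± 0.13), Grn (0.78 ± 0.15), Ctss (1.65 ± 0.30) and Ctsz (0.73 ± 0.16) were higher, 3 of 5 and 5 of 17 tested. Both lists shifted with an estimated correlation (adjusted p = 0.000145 and adjusted p = 0.000804). Oligodendrocyte genes were lower as a list (median -0.30, adjusted p = 0.00834 with an estimated correlation) with 0 of 15 passing singly by edgeR. The ribosomal protein list's downward call was lost (adjusted p = 0.654 with an estimated correlation). Without the Sall1 libraries holding Y-linked counts the calls of C1qb (0.62), Ctss (0.56), Grn (0.64), Ctsz (0.59) and Lyz2 (-1.17) were lost, with adjusted p between 0.0504 and 0.335, and a term for this pattern took C1qb to 0.87 and Ctss to 0.90. With libraries summed over a shared first number the calls of C1qb (1.46), Lgmn (0.797), Grn (0.81), Ctss (1.67), Ctsz (0.75), Lyz2 (-1.07) and Rpl7 (-1.08) were lost, with adjusted p between 0.0584 and 0.321. These values stayed close to those of the main fit.

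The IgG precipitates of the lines did not differ in any gene by edgeR, with 0 of 9619 past the threshold and 644 at an unadjusted p under 0.05. DESeq2 called 14 and limma-voom 0. With edgeR, 322 passed with a term for Y-linked counts, 63 without the Sall1 libraries that hold them and 17 without those with the first number 3, so the backgrounds of the lines are not shown to be alike. The immediate early list was higher in Sall1 IgG by camera (adjusted p = 0.0119), a call lost with an estimated correlation (adjusted p = 0.399).

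The difference of the enrichments over IgG was tested as an interaction. Enrichment was higher in Sall1 mice for 20 genes and lower for 1, Pf4 (-3.68 ± 0.65, adjusted p = 0.00296). The genes with higher enrichment included Slc2a5 (2.615 ± 0.48), Trem2 (2.175 ± 0.26), Tmem119 (2.02 ± 0.28), Laptm5 (1.999 ± 0.27), Crybb1 (1.94 ± 0.33), C1qa (1.66 ± 0.25), Selplg (1.57 ± 0.22) and C1qc (1.34 ± 0.24). Of 25 microglial genes 9 passed, and 17 adjusted over the list alone, with a median difference of 1.28 (adjusted p = 1.35e-05 with an estimated correlation). The complement (adjusted p = 0.00121) and lysosomal (adjusted p = 0.00199) lists also shifted with an estimated correlation. The border macrophage list's call was lost (adjusted p = 0.194 with an estimated correlation), as was that of the ribosomal protein list (adjusted p = 0.587). With libraries summed over a shared first number 4 genes passed. The calls of Slc2a5 (2.62), Crybb1 (1.93), Laptm5 (1.99), C1qa (1.63) and C1qc (1.34) were lost at differences close to those of the main fit, with adjusted p between 0.0516 and 0.274. Without the Sall1 libraries holding Y-linked counts edgeR called 0 genes, with 516 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 5. All the genes named here lost their edgeR calls, from Pf4 (-3.41) to C1qc (0.77), with adjusted p between 0.146 and 0.908, and kept their direction. This setting keeps 2 HA and 2 IgG libraries of Sall1 mice. Loss of calls through fewer libraries is therefore not told apart from an effect of the pattern.

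After LPS, Pf4 was again among the genes most enriched in Lyve1 HA, at 33.1 ± 14.3 CPM against 2.13 ± 1.76 CPM in IgG (n = 4 each), a log2 ratio of 3.62 ± 0.48 (adjusted p = 8.13e-06). The secreted protein gene Mia (2.83 ± 0.67), the acute phase gene Saa3 (2.78 ± 0.21), Lyz2 (2.62 ± 0.50), the haptoglobin gene Hp (2.33 ± 0.51), the keratin gene Krt18 (2.17 ± 0.54) and the macrophage gene Cd68 (2.14 ± 0.37) followed. Saa genes are similar in sequence, so the values of Saa3 are uncertain. Without Lyve1 LPS IgG library 2-2 the ratios were 4.03 for Mia, 3.61 for Lyz2 and 2.94 for Hp. Lower in HA were Atrip (-5.69 ± 0.66, or -6.40 without LPS HA library 2-2), Cep290 (-4.27 ± 0.52), Ppfibp1 (-3.415 ± 0.52), the splicing factor gene Rbm25 (-3.08 ± 0.38), Trex1 (-3.045 ± 0.32) and Mzf1 (-2.38 ± 0.31). Of 9680 genes tested, 931 passed, 505 higher and 426 lower, with 106 at least 2-fold higher and 118 at least 2-fold lower. The count was 535 without LPS IgG library 2-1, 548 without IgG library 1-1 and 567 without HA library 1-2. It was 443 with libraries summed over a shared first number, which ended the call of Ppfibp1 (adjusted p = 0.0724).

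Complement genes were higher in HA after LPS in 6 of 9 cases, 7 adjusted over the list alone, with a median of 1.32 (adjusted p = 0.00484 with an estimated correlation). C1qc (1.44 ± 0.18), C1qa (1.32 ± 0.19), C1qb (1.61 ± 0.26) and the factor B gene Cfb (2.02 ± 0.46) led. In the lysosomal list 8 of 17 were higher, 12 adjusted over the list alone, with Grn (1.35 ± 0.21), Ctsz (1.16 ± 0.19) and Laptm5 (1.38 ± 0.23) among them (adjusted p = 0.00484). In the microglial list 8 of 22 were higher, including Fcer1g (1.24 ± 0.25) and Tmem119 (1.02 ± 0.26), with adjusted p = 0.0183. Pf4 and Lyz2 passed of 12 border macrophage genes (adjusted p = 0.0475). The fibroblast genes Ptgds (0.93 ± 0.12), Apod (0.95 ± 0.16), Igfbp2 (1.03 ± 0.18) and Mgp (1.05 ± 0.23) passed of 9 (adjusted p = 0.0183). The endothelial genes Ly6a (0.98 ± 0.20), Ly6c1 (0.97 ± 0.21), Bsg (0.67 ± 0.16) and Cldn5 (0.73 ± 0.22) passed of 15 (adjusted p = 0.0482). These 6 values, and those of the choroid plexus (0.0382), disease-associated (0.00824) and neutrophil (0.0431) lists, are camera's with an estimated correlation. The call of Cldn5 was lost without LPS HA library 2-2 (0.49) or IgG library 1-2 (0.74), 2-1 (0.65) or 2-2 (0.71), with adjusted p between 0.0507 and 0.147, and with limma-voom (0.55) or sums over a shared first number (0.64).

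Lcn2, an iron-carrier binding protein gene, was the neutrophil gene that passed (1.29 ± 0.20). Among interferon-stimulated genes Ly6e (1.13 ± 0.19), Ifi27l2a (1.79 ± 0.31) and Ifitm3 (1.10 ± 0.22) passed of 22. The calls of the interferon-stimulated, NF-kB and mural cell lists were lost with an estimated correlation (adjusted p = 0.515, adjusted p = 0.264 and adjusted p = 0.12).

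The largest change in Lyve1 HA after LPS was that of the acute phase gene Saa3. It rose from 1.39 ± 0.851 CPM (n = 6) to 3768 ± 355 CPM (n = 4), a log2 change of 11.17 ± 0.31 (adjusted p = 1.97e-20). Lcn2 rose from 1.10 ± 1.43 to 1014 ± 214 CPM (9.43 ± 0.30). The granulocyte growth factor gene Csf3, with 0 counts at steady state, was at least 170-fold higher against a floor of 3 counts over the group, and its call was lost with libraries summed over a shared first number (adjusted p = 0.101). The stromelysin gene Mmp3 was at least 20.3-fold higher and Saa2, which may share reads with its near copy Saa1 and is uncertain, at least 27.6-fold. The collagen gene Col5a3, with 3 counts at steady state, had a ratio of 91.3 (95% counting interval 30.8 to 446). The metalloprotease inhibitor gene Timp1 (6.29 ± 0.44) and Ctla2a (5.85 ± 0.28) also rose. Without steady-state HA library 2-1 the changes of Lcn2 and Timp1 were 10.31 and 7.47, and the fitted change of Col5a3 went from 6.29 to 7.13.

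**Figure D3:**
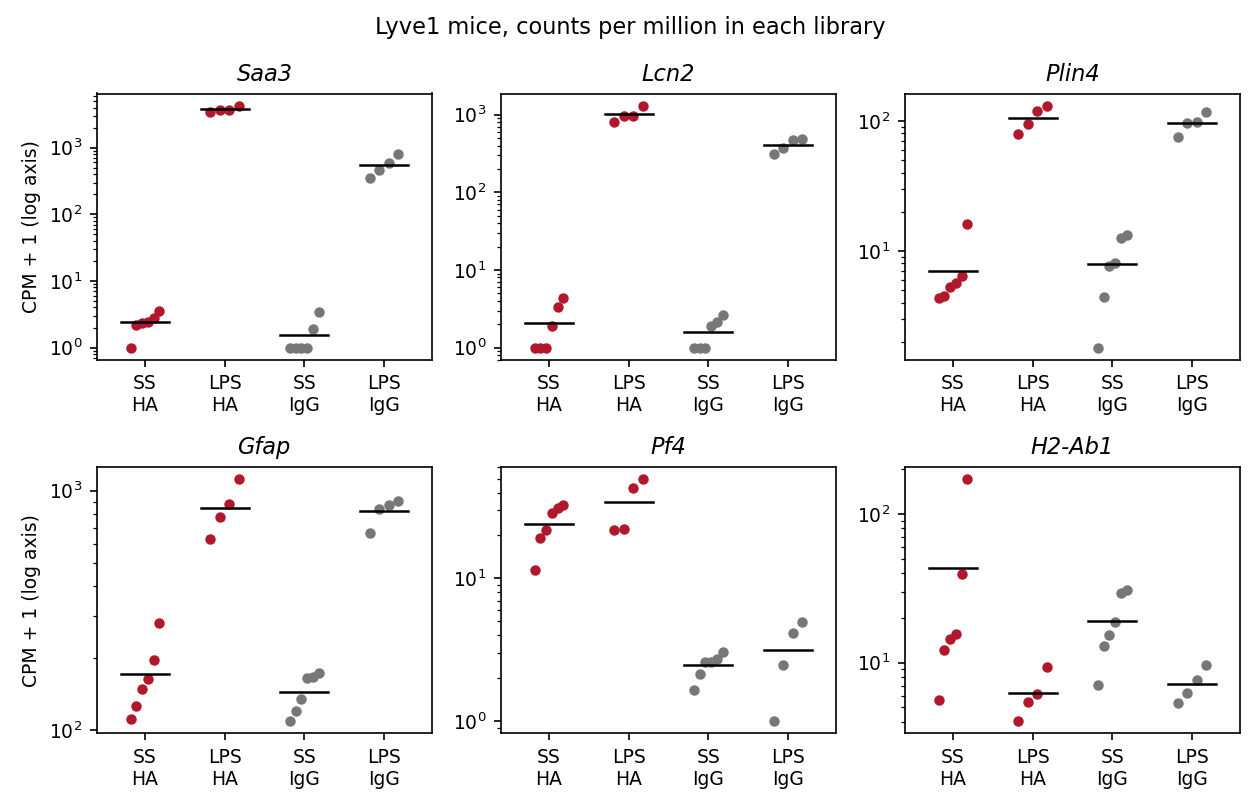
CPM plus 1 on a log axis of 6 genes in each Lyve1 library at steady state and after LPS, with the line at the group mean. Saa3 rose from 1.39 to 3768 CPM in HA and from 0.548 to 546 CPM in IgG, and Gfap from 170 to 848 CPM in HA.

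Srsf3, a splicing factor gene, fell in Lyve1 HA after LPS (log2 change -2.39 ± 0.38, or -2.975 without LPS HA library 1-1). The myelin lipid enzyme gene Ugt8a (-2.31 ± 0.50), the nuclear receptor gene Nr4a3 (-2.29 ± 0.35), Lrrc75a (-2.10 ± 0.44), the somatostatin receptor gene Sstr2 (-2.06 ± 0.43) and the myelin genes Opalin (-1.99 ± 0.26) and Pllp (-1.98 ± 0.19) fell too. In all 1690 of 9680 genes passed, 916 higher and 774 lower, with 425 at least 2-fold higher and 248 at least 2-fold lower. The count was 1044 without LPS HA library 1-2 and 1096 without 2-2, and 1126 with libraries summed over a shared first number. The LPS libraries all held Y-linked counts and the Lyve1 libraries at steady state did not, so treatment and this pattern go together.

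NF-kB and cytokine genes rose in Lyve1 HA in 13 of 15 cases, also adjusted over the list alone, with a median of 2.60 and the same median with Csf3 at its bound (adjusted p = 0.000155 with an estimated correlation). Bcl3 rose by 4.001 ± 0.45 (4.62 without steady-state HA library 3-2), the cytokine signalling inhibitor gene Socs3 by 2.51 ± 0.30 and the chemokine gene Ccl5 by 4.73 ± 0.47. Of 22 interferon-stimulated genes 20 rose, with a median of 1.85 (adjusted p = 0.00723), among them Ifitm3 (2.96 ± 0.22), the nucleic acid sensor gene Zbp1 (4.56 ± 0.47), Tap1 (2.46 ± 0.36) and Ifi27l2a (1.88 ± 0.26). Of 17 glucocorticoid and metallothionein genes 11 rose, 12 adjusted over the list alone, with a median of 1.56 (adjusted p = 1.42e-06), including the lipid droplet gene Plin4 (4.10 ± 0.32), Map3k6 (2.88 ± 0.25), Mt1 (2.30 ± 0.17) and the cell cycle inhibitor gene Cdkn1a (2.27 ± 0.18). Complement genes rose in 8 of 9 cases (median 1.26, adjusted p = 0.000545), with C3 at 4.19 ± 0.45, Cfb at 4.66 ± 0.51, Serping1 at 2.42 ± 0.30 and C1qa at 1.26 ± 0.17. Without steady-state HA library 2-1 the changes were 5.603 for Ccl5, 6.24 for Zbp1 and 5.63 for Cfb, and limma-voom gave 5.49 for Ccl5. The list values in this paragraph are those with an estimated correlation.

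Oligodendrocyte genes fell in Lyve1 HA, 9 of 15 and 12 adjusted over the list alone, with a median of -0.705 (adjusted p = 7.07e-05 with an estimated correlation). Qdpr (-1.44 ± 0.13) and Cryab (-0.70 ± 0.13) fell beside Opalin and Pllp. The precursor genes Gpr17 (-1.49 ± 0.27), C1ql1 (-0.99 ± 0.20), Olig1 (-0.50 ± 0.13) and Cspg4 (-0.83 ± 0.26) fell of 8, and the list's call was lost with an estimated correlation (adjusted p = 0.155). The call of Cspg4 was lost without steady-state HA library 2-2 (-0.64, adjusted p = 0.0749) or LPS HA library 2-2 (-0.70, adjusted p = 0.079), with limma-voom (-0.635), with only the groups compared (-0.835) and with sums over a shared first number (-0.785). Endothelial genes rose in 8 of 15 cases, including Ly6a (2.89 ± 0.19), Ly6c1 (2.06 ± 0.19) and Cldn5 (1.77 ± 0.20), while Itm2a fell (-1.74 ± 0.33), and the list's shift held (adjusted p = 0.00629 with an estimated correlation). Astrocyte genes rose in 6 of 18 cases, with Gfap (2.30 ± 0.20), Sox9 (1.49 ± 0.34) and Fgfr3 (0.92 ± 0.16) among them (adjusted p = 0.012 with an estimated correlation). The fibroblast list's call was lost (adjusted p = 0.0503 with an estimated correlation), with Apod (2.39 ± 0.15), Dcn (1.44 ± 0.24), Mgp (0.84 ± 0.20) and Ptgds (0.51 ± 0.11) higher. The neuronal list's downward call was lost as well (adjusted p = 0.0979 with an estimated correlation), with Olfm1 (-0.73 ± 0.15) and Stmn2 (-0.75 ± 0.18) lower.

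Among macrophage lists, Cp (3.23 ± 0.32), C4b (2.42 ± 0.29) and Ms4a6c (2.37 ± 0.40) rose of 12 members of the border macrophage list (adjusted p = 0.0243 with an estimated correlation). These genes also rose in IgG, and C4b was lower in HA than in IgG at steady state. Their rise is therefore not shown to be one of border macrophages. The microglial list did not shift (camera adjusted p = 0.575), with Fcer1g (1.67 ± 0.22) and Itgam (1.86 ± 0.31) higher and Ltc4s (-1.19 ± 0.25) lower of 22. In the lysosomal list 8 of 17 rose, including Ctsl (1.196 ± 0.15), Ctsz (1.26 ± 0.16), Grn (0.97 ± 0.17) and Ctsc (1.59 ± 0.41, or 2.21 without steady-state HA library 2-1), and Hexa fell (-0.46 ± 0.15; adjusted p = 0.0234 for the list with an estimated correlation). The call of Hexa was lost without steady-state HA library 2-1 (-0.44), 2-2 (-0.41), 3-1 (-0.42) or 3-2 (-0.43) or LPS HA library 1-1 (-0.37), 1-2 (-0.48) or 2-1 (-0.36), with adjusted p between 0.0549 and 0.146. Spp1 (2.41 ± 0.29), Cd63 (0.82 ± 0.15) and Cd9 (0.90 ± 0.20) rose of 14 disease-associated genes, and the list's call was lost (adjusted p = 0.0503 with an estimated correlation). Lcn2 and S100a9 (2.04 ± 0.64) rose of 5 neutrophil genes (adjusted p = 0.00629 with an estimated correlation). The call of S100a9 was lost without steady-state HA library 1-1 (1.87), 2-1 (1.89), 3-1 (1.87) or 3-2 (1.81) or LPS HA library 2-1 (2.04) or 2-2 (1.48), with adjusted p between 0.062 and 0.146, and its change was 2.65 without steady-state HA library 2-2. It was also lost with DESeq2 (1.94), with only the groups compared, as was that of Hexa, and with sums over a shared first number.

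MHC class II genes were lower after LPS in 3 of 5 cases, H2-Eb1 (-2.30 ± 0.69), H2-Ab1 (-3.04 ± 0.95) and H2-Aa (-2.53 ± 0.82), and the list did not shift (camera adjusted p = 0.101). H2 genes are similar in sequence, so these values are uncertain. Steady-state HA library 2-1 held 171 CPM of H2-Ab1, and without it the changes were -1.68 for H2-Eb1 (adjusted p = 0.0588), -1.51 for H2-Ab1 (adjusted p = 0.0418) and -1.58 for H2-Aa (adjusted p = 0.0826). The calls of H2-Ab1 and H2-Aa were also lost without steady-state HA library 2-2 (-3.07 and -2.43) or LPS HA library 1-2 (-2.94 and -2.51), 2-1 (-3.002 and -2.76) or 2-2 (-2.92 and -2.41). Those of H2-Eb1 and H2-Aa were lost without LPS HA library 1-1 (-2.26 and -2.50), and that of H2-Eb1 without 1-2 (-2.27), 2-1 (-2.57) or 2-2 (-2.14). The adjusted p in these 13 cases lay between 0.0501 and 0.108. All 3 calls were lost with limma-voom (-1.72 for H2-Eb1, -1.89 for H2-Ab1 and -1.63 for H2-Aa) and with sums over a shared first number, and those of H2-Ab1 and H2-Aa with only the groups compared. That of H2-Aa was lost without the LPS IgG library with the lowest total as well (adjusted p = 0.0506).

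Ribosomal protein genes fell in 25 of 71 cases and 35 adjusted over the list alone, among them Rpl3 (-0.83 ± 0.14), Rpl13a (-0.72 ± 0.13) and Rpl7 (-1.01 ± 0.20), while Rps15a rose (1.13 ± 0.23). The median was -0.44, and the list's call was lost with an estimated correlation (adjusted p = 0.129). By its median this list had stood higher in HA than in IgG at steady state. A loss of that difference between sets of libraries was not told apart from a fall in the tagged cells. Immediate early and heat shock genes did not shift as a list (camera adjusted p = 0.848), with Egr1 (-1.32 ± 0.18) and Nr4a1 (-1.41 ± 0.22) lower and Ier3 (1.36 ± 0.20) and Klf6 (1.14 ± 0.24) higher. Mural cell (0.575) and choroid plexus (0.796) genes did not shift either.

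The same LPS contrast in the IgG precipitates measured the background of the whole tissue. Saa3 rose from 0.548 ± 0.979 CPM (n = 6) to 546 ± 196 CPM (n = 4), by 9.71 ± 0.34 on the log2 scale (adjusted p = 5.46e-18), or by 10.92 without steady-state IgG library 2-2. Lcn2 rose by 9.30 ± 0.33, and Csf3, with 0 counts at steady state, was at least 155-fold higher against the same floor, a call lost with libraries summed over a shared first number (adjusted p = 0.132). The matrix genes Pamr1 (-2.77 ± 0.40), Fmod (-2.34 ± 0.36) and Myoc (-2.17 ± 0.35) and the precursor gene Gpr17 (-2.11 ± 0.31) fell. Of 9680 genes, 1293 passed, 670 higher and 623 lower, with 345 at least 2-fold higher and 114 at least 2-fold lower. Of the 916 genes higher in HA, 315 were also higher in IgG, where independent lists would share 63.4, and 10 were lower. Of the 774 lower in HA, 140 were also lower in IgG, where independent lists would share 49.8.

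**Figure D4:**
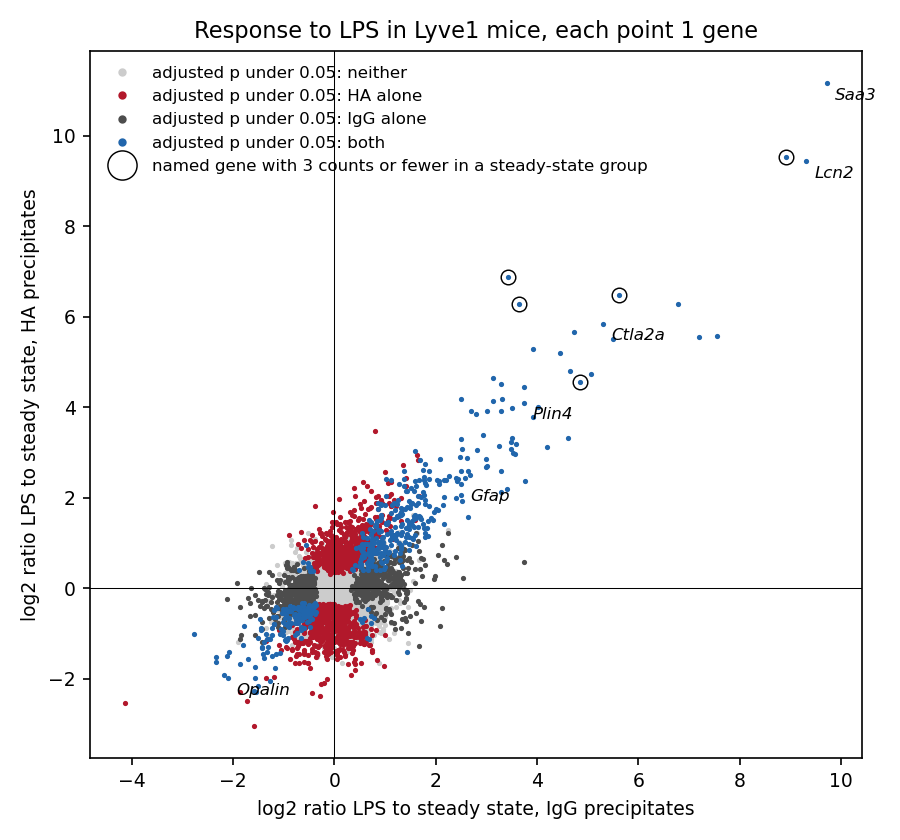
Log2 ratio of LPS to steady state in HA against that in IgG for each of 9680 genes, coloured by which contrast passed, with circles around named genes whose fitted ratio rests on 3 counts or fewer at steady state. Across the 673 genes called at least 2-fold changed in HA, 557 had the same sign in IgG.

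In IgG, 12 of 15 NF-kB and cytokine genes rose, 13 adjusted over the list alone, with Bcl3 (4.01 ± 0.45) and Socs3 (2.68 ± 0.30) among them. The median was 2.41, and 2.41 with Csf3 and Cxcl1 at their bounds (adjusted p = 0.000429 with an estimated correlation). Of 22 interferon-stimulated genes 20 rose (median 2.01, adjusted p = 0.0128), including Ifitm3 (3.56 ± 0.27) and Zbp1, whose 3 counts at steady state gave a ratio of 38.2 (95% counting interval 12.2 to 193). Of 17 glucocorticoid and metallothionein genes 10 rose (median 0.91, adjusted p = 6.92e-06), including Plin4 (3.74 ± 0.31), Fkbp5 (1.59 ± 0.15) and Map3k6 (2.62 ± 0.25). Of 15 oligodendrocyte genes 9 fell (median -0.65, adjusted p = 0.000816), including Cnp (-1.03 ± 0.13), Qdpr (-1.06 ± 0.13), Pllp (-1.56 ± 0.20) and Opalin (-2.10 ± 0.30). The astrocyte list rose (adjusted p = 0.0294), with Gfap at 2.51 ± 0.20, and so did the complement (0.0424) and neutrophil (0.00688) lists, with C3 at 2.51 ± 0.44. All these list values are with an estimated correlation.

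The border macrophage genes Cp (3.50 ± 0.33), Ms4a6c (3.76 ± 0.51) and C4b (1.02 ± 0.28) rose in IgG of 12, and the list's call was lost (adjusted p = 0.0598 with an estimated correlation). The call of C4b was lost without LPS IgG library 2-2 (0.94, adjusted p = 0.0685). Among endothelial genes Ly6a (2.47 ± 0.22), Ly6c1 (1.77 ± 0.22) and Cldn5 (1.31 ± 0.22) rose. The calls of the endothelial, fibroblast, mural cell and oligodendrocyte precursor lists were lost with an estimated correlation (adjusted p = 0.173 each), as were those of the immediate early (adjusted p = 0.184), MHC class II (adjusted p = 0.335) and ribosomal protein (adjusted p = 0.531) lists. The microglial list did not shift (camera adjusted p = 0.13).

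The interaction asked which genes responded to LPS differently in HA and in IgG. It called 313 genes, 159 higher and 154 lower, with 61 at least 2-fold higher and 100 at least 2-fold lower. The named differences included those of Ppfibp1 (-3.16 ± 0.75, adjusted p = 0.0314), Rbm25 (-2.94 ± 0.51) and the hypoxia factor gene Hif3a (2.66 ± 0.58). Hif3a rose by 3.47 in HA and by 0.81 in IgG. Ppfibp1 and Rbm25 were not among the genes called at least 2-fold changed in HA that changed more there than in IgG. A fall of that size in HA is therefore not shown for them. Ribosomal protein genes were lower in 15 of 71 cases and 29 adjusted over the list alone, including Rpl27a (-1.285 ± 0.24), Rpl13a (-0.95 ± 0.18), Rpl17 (-0.95 ± 0.20) and Rpl7 (-1.30 ± 0.27). Their median was -0.54, and the list's call (camera adjusted p = 7.44e-15) was lost with an estimated correlation (adjusted p = 0.39), like those of the lysosomal (adjusted p = 0.39) and endothelial (adjusted p = 0.479) lists, in which 0 of 17 and 0 of 15 genes passed by edgeR. The call of Ppfibp1 was lost without steady-state HA library 1-2 (-3.11) or 2-1 (-3.11), steady-state IgG library 1-1 (-3.12) or LPS HA library 1-2 (-2.77), with adjusted p between 0.0513 and 0.0573, and its value was -2.57 without LPS IgG library 2-1. The count was 890 without LPS HA library 1-1, 127 without 1-2 and 187 without 2-2, 207 without steady-state HA library 1-2, and 177, 175 and 190 without LPS IgG library 1-1, 1-2 and 2-1. It was 543 with DESeq2, 502 with limma-voom and 70 with libraries summed over a shared first number, which ended the calls of Ppfibp1, Rpl13a and Rpl17.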

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

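The tests of Y-linked counts and of the first number were chosen after the result was seen, and so were the test of shared Atrip and Trex1 reads, that of carried-over RNA and that of precipitation irrespective of the line. Of 48 groups of values from reported genes, 4 held a library far from the others, where chance gives about 1 in 20 groups, or 2.4. Trem2 stood at 22.9 CPM in Sall1 IgG library 1-2 against 26.5 to 28.1 in the others. Saa3 stood at 2.41 CPM in Lyve1 steady-state IgG library 2-2 against 0 to 0.872, and Plin4 at 15 CPM in Lyve1 steady-state HA library 1-1 against 3.33 to 5.44. H2-Ab1 stood at 171 CPM in Lyve1 steady-state HA library 2-1 against 4.61 to 38.7, which takes the group's mean from 16.5 to 42.2 CPM.

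The enrichment of HA over IgG differed between the lines for 21 genes by the interaction test. Among these were Pf4 (-3.68), Slc2a5 (2.615), Trem2 (2.175), Tmem119 (2.02), Laptm5 (1.999), Crybb1 (1.94), C1qa (1.66), Selplg (1.57) and C1qc (1.34). The response to LPS differed between HA and IgG for 313 genes. Among these were Ppfibp1 (-3.16), Rbm25 (-2.94), Hif3a (2.66), Rpl7 (-1.30), Rpl27a (-1.285), Rpl13a (-0.95) and Rpl17 (-0.95). The call of Ppfibp1 was lost without Lyve1 steady-state HA library 1-2 (-3.11) or 2-1 (-3.11), steady-state IgG library 1-1 (-3.12) or LPS HA library 1-2 (-2.77), and its value was -2.57 without LPS IgG library 2-1. The count of 313 went to 890, 127 and 187 without LPS HA library 1-1, 1-2 and 2-2, to 207 without steady-state HA library 1-2, and to 177, 175 and 190 without LPS IgG library 1-1, 1-2 and 2-1.

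Atrip was higher in each of the 16 IgG libraries (lowest 255.2 CPM) than in any of the 16 HA libraries (highest 217.6 CPM), while Trex1, which overlaps it, was called lower in HA but reached 121.7 CPM in an HA library against a lowest of 94.55 CPM in IgG. The highest group median of Trex1 excess per Atrip excess among the IgG groups was 2.32 times the lowest. It was 0.132 after LPS (0.119 to 0.138) and 0.306 in Sall1 mice (0.2 to 0.423), which argues against the same fixed share of reads passing from Atrip to Trex1 in both. At steady state the Lyve1 libraries (median 0.256, 0.236 to 0.348) overlapped those of Sall1 mice, so a fixed share there stays open. Steady-state IgG libraries that share a first number lay closer in Atrip than other pairings (exact one-sided permutation p = 0.00889 over 225 arrangements), which was not tested after LPS, where libraries 1-1 and 1-2 held 4907 and 5260 CPM and 2-1 and 2-2 held 5513 and 3039 CPM. The IgG libraries with Y-linked counts held 2404 to 8982 CPM of Atrip and those without 255.2 to 1343 CPM, so a batch marked by the number and whatever goes with the Y-linked pattern, sex of the mice included, may each set the level. In Sall1 mice the number and this pattern go together, and the origin of the signal stays open.

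The genes changed at least 2-fold by LPS in Lyve1 HA were set against sex and carried-over RNA, since all LPS libraries held Y-linked counts. The Lyve1 libraries at steady state fell below the set threshold of 10, with at most 2 counts each of Ddx3y and Eif2s3y. Sall1 libraries with and without Y-linked counts, none of them after LPS, were compared over 555 autosomal and X-linked genes. In the direction of the LPS change, the median difference was -0.156 in HA (quartiles -0.561 and 0.22) and -0.238 in IgG. In HA this was -0.134 of the median LPS change, so these genes as a set did not follow the Y-linked pattern of Sall1 mice. That pattern goes with the first number there, in 4 HA libraries against 2, so sex cannot be told apart from a batch. A part played by sex in the Lyve1 mice, or in their response to LPS, stays open. Ddx3y and Eif2s3y, which differed by at least 3.75 on the log2 scale with Y-linked counts in Sall1 mice, may reflect sex alone. Of 673 genes changed at least 2-fold in HA, 557 had the same sign in IgG (r = 0.842), and 7.28% changed more in HA by the interaction test, with a median change of 1.36 in HA, where choosing genes by size enlarges it, and 0.727 in IgG. A response of the tagged cells cannot be told apart from RNA of other brain cells carried into the HA precipitate for most of these genes, because untagged RNA in HA was not measured on its own.

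Outside the macrophage lists, the ratio of HA to IgG correlated between Sall1 and Lyve1 mice at steady state, which share no libraries (r = 0.645 over 9540 genes, 0.558 to 0.73 with 1 library left out). In Lyve1 mice HA libraries tended to be shallower than IgG at steady state and deeper after LPS, so depth as the whole cause asks for a negative correlation between these states. It stayed positive (r = 0.282, 0.172 to 0.357 with 1 library left out), which argues against that, while a part played by depth stays open. Over all genes tested, those of the macrophage lists included, 313 of the 463 genes higher in Sall1 HA were also higher in Lyve1 HA, where independent lists would share 54. Of the 480 lower, 413 were also lower against 67.4. Binding of RNA to either antibody irrespective of the line may account for this part, and so may transcripts common to both tagged cell types, which stay open.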

How the results depend on the processing

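The sums over a shared first number, the settings on Y-linked counts or on chosen Sall1 libraries, and all settings for IgG between the lines were chosen after the result was seen. With these sums the counts fell to 163 (Sall1 HA against IgG), 1005 (Lyve1), 29 (HA between lines), 4 (enrichment between lines), 443 (HA against IgG after LPS), 1126 (LPS in HA) and 70 (LPS enrichment). Without Sall1 libraries holding Y-linked counts they were 69, 900 for HA between lines (78 shared), 0 for enrichment by edgeR (516 at an unadjusted p under 0.05, DESeq2 5, limma-voom 0) and 63 for IgG, and Sall1 between lines in HA turned to -0.0131, never having passed. Only Sall1 libraries 3-1 and 3-2 of HA and of IgG are kept there. A Y-linked term gave 1775 (116 shared) and 322 for HA and IgG between lines. Without the first number 3, enrichment had 32 and IgG 17. Without Sall1 IgG 2-1 and 2-2, enrichment had 13. The IgG library with its own number was the best partner of an HA library in 2 of 6, 2 of 6 and 2 of 4 cases (Lyve1, Sall1, Lyve1 after LPS) and one with its own first number in 6 of 6, 4 of 6 and 3 of 4, with a mean r of 0.263, 0.231 and 0.0818 for the same number against -0.14, -0.115 and -0.069 for another first number, so the first number groups steady-state libraries and full pairing is not shown. After LPS, HA libraries sharing it were less alike than others (mean r -0.482 against -0.227) and IgG libraries more alike (-0.132 against -0.419). A block on the numbers gave 209 for HA between lines, 705 for LPS enrichment and 1 for IgG between lines. LPS enrichment had 543 with DESeq2, 502 with limma-voom and 175 without the library under the set share of the median total, and its higher calls went from 159 of 313 to 259 of 395 (65.6%) with library totals. IgG between lines had 14 with DESeq2, and Sall1 HA against IgG had 541 with only the groups compared. Leaving out 1 library at a time gave 567 to 1135, 2071 to 2335, 90 to 196, 16 to 26, 535 to 1102, 1044 to 2324, 875 to 1340, 127 to 890 and 0 to 0 for Sall1, Lyve1, HA between lines, enrichment, LPS HA against IgG, LPS in HA, LPS in IgG, LPS enrichment and IgG between lines. List shifts went from 74 of 160 to 39 with an estimated correlation, 71 with fry and 70 with totals. Of 2361 values of named genes over the settings 2266 kept their direction and their call or lack of one, whatever their size, 94 lost their call and 1 reversed, and of 2790 with 1 library left out 58 lost it. The cause was not tested. The 3 planned results on Sall1 mice after LPS were not run, only the groups compared was not run for interactions, where it is identical, and settings for normalized values did not apply to counts.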

Other observations

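The splits of libraries were planned for the planned results, and the comparison of IgG between the lines was chosen after the result was seen. With each library taken as a separate unit, other splits of the same libraries exclude chance for the counts of Lyve1 HA against IgG (2472, highest other 188), HA between lines (135, highest other 10), HA against IgG after LPS (931, highest other 52), LPS in HA (1690, highest other 1101) and LPS in IgG (1293, highest other 369), where 1 split, the real one, gave as many. The real split alone also gave as many for enrichment between lines (21, highest other 1) and LPS enrichment (313, highest other 0). There the other splits mix lines or treatments in HA and IgG alike. Differences between lines or treatments then enter the spread and keep calls few with or without an interaction, so the splits do not decide these counts. Steady-state libraries of a group that share a first number were more alike (mean r 0.165 to 0.436) than others (-0.348 to -0.274). With these sets as units the 2 or 3 per group leave too few splits to exclude chance by splits. The edgeR fits on counts summed over these sets still called genes, among them 1005 for Lyve1 HA against IgG, 443 after LPS and 1126 for LPS in HA. After LPS this grouping was not seen in HA (-0.482 against -0.227) and was in IgG (-0.132 against -0.419). For Sall1 HA against IgG, 2 of 100 splits gave as many (943, highest other 1373). The larger split put Sall1 HA libraries 1-1 to 2-2 with IgG libraries 2-1 and 2-2, which points to a structure of the samples. On the first principal component, with 23.3% of the variance, these 2 IgG libraries (-6.82 and -13.6) lay among the HA libraries (-36.1 to -3.46) and apart from the other IgG libraries (16.3 to 27.3). Without them Sall1 HA against IgG had 1300 genes, 802 of them among the 943, and the enrichment between lines had 13. Without the first number 3, 705 genes passed, and without the libraries holding Y-linked counts 69 did. For IgG between lines the splits decide nothing, since with a real count of 0 each of the 100 splits gives as many.

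The authors' pass marks went to genes changed at least 2-fold with an adjusted p under 0.05, while the calls here rest on adjusted p alone. Both rest on the same counts. Of the genes called here and changed at least 2-fold, 162 of 163 held the mark in Sall1 HA against IgG and 409 of 411 in Lyve1. These were 72 of 74 in HA between lines and 207 of 224 in HA against IgG after LPS. For the response to LPS they were 634 of 673 in HA and 419 of 459 in IgG. Of the 182 genes the authors passed in Sall1 HA against IgG, 165 were tested and 164 passed here. In the response to LPS 644 of 664 tested passed in HA and 425 of 433 in IgG. In Lyve1 HA against IgG 421 of 427 did, after LPS 211 of 223, and in HA between lines 72 of 80.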
